A study of Mus musculus with 14 samples.

How the data were processed

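RNA was measured by sequencing in kidney cortex of 14 mice. Per the labels' protocols, mice of the C57BL/6 background were placed at random on a vitamin A sufficient regular chow or a vitamin A deficient (VAD) diet 2 weeks after weaning, and organs were taken after 24 weeks. Cortex pieces were kept in RNAlater, total RNA was extracted on columns, and libraries were read as 51-base single-end reads on a HiSeq2000. The labels place the libraries in 4 groups: wild type on chow (WT, n = 3), transgenic on chow (TRACK, n = 4), wild type on the deficient diet (WT-VAD, n = 3) and transgenic on the deficient diet (TRACK-VAD, n = 4). The labels speak of 4 mice per cohort and number the libraries as biological replicates, so each library was taken as a separate mouse. Lane labels put all WT and TRACK libraries and TRACK-VAD libraries 1 to 3 in lane 5, and TRACK-VAD library 4 and all WT-VAD libraries in lane 6.

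The authors deposited an expression table in FPKM (fragments scaled for transcript length and library size) for protein-coding gene loci, with 22053 rows and 22007 gene IDs. It also held 6 columns of per-sample values that match no library label of this series, and these were not used. The authors also deposited 6 tables of their own comparisons, which per the file headers hold a mean normalized count signal, a log2 fold change with its standard error, and p-values. Per the submitters' processing notes the tools and builds named are DESeq 1.32 and mm9; the aligner and the program that computed FPKM are not given in the sources used here. The gene loci of the FPKM table were compared with GENCODE vM21 on GRCm38. Of 22053 rows, 21887 had their gene ID there, 21869 overlapped that gene, and 16887 had an identical start and end after 1 was added to the table's start. The build named in the notes and the loci in the table therefore differ, and coordinates are given as in the table, counted from 1.

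FPKM values are not counts. Whole read counts were not recovered from them and the absolute depth is unknown, so no counting interval is given. Relative depth was estimated from 1829 genes under 0.15 FPKM, where a gene with equal reads in both libraries of a pair has an FPKM ratio set by their depths. The modes of these ratios fitted 1 depth per library within 0.1 (log2) in 90 of 91 pairs. Depth ran from 0.82 to 1.29 times the geometric mean of all libraries. The summed FPKM per library ran from 2012358 to 2551968, and 11206 to 12277 genes per library reached 1 FPKM. Gpx3 alone made up 62.8% to 71.2% of the sum. All 14 selenoprotein genes looked at, among them Gpx3, Gpx4, Sepp1 and Txnrd1, had FPKM that were high for their mean count in the authors' deposited tables: the ratio lay at the 96.2 to 99.4 percentile of all genes. Levels of these genes were therefore not compared with those of other genes. Because 1 gene dominated the FPKM sum, values were scaled between libraries.

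The design fixed before the data were examined named a count-based test, and limma for files without counts; because the table holds FPKM, limma was used throughout. One row was kept per gene ID. Genes with at least 1 FPKM in at least 3 libraries were tested. After the values were seen, 17 genes were left out because a library was listed at 0 while another library of its group and at least 7 libraries had 5 FPKM or more. This left 12251 genes. Scale factors were trimmed means of log ratios (30% of ratios and 5% of levels trimmed, without weights), computed on the FPKM of these genes, and ran from 0.897 to 1.18. FPKM divided by the factor are called scaled FPKM, and all means and SDs are of these. Genes were tested on log2(scaled FPKM + 1) with limma 3.58.1 in R 4.3.3 (moderated test with a mean-variance trend), with all 14 libraries in a model of the 4 group means. A gene was called at a Benjamini-Hochberg adjusted p at or under 0.05; tests were two-sided. The pseudocount of 1 FPKM makes fold changes of genes with low values smaller than the ratio of their means. Gene levels come from reads without stated strand information, so reads of overlapping or near-identical genes, such as Cyp2a4 and Cyp2a5, Hba-a1 and Hba-a2 or Acaa1a and Acaa1b, may have been divided between them. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

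Comparisons were TRACK with WT, TRACK-VAD with WT-VAD, WT-VAD with WT, TRACK-VAD with TRACK, the averages of genotype over diets and of diet over genotypes, their interaction, and as counts only TRACK-VAD with WT and TRACK with WT-VAD. Before the data were examined, 34 gene lists were written for energy metabolism, mitochondria, stress responses, retinoid genes, nephron segments, other cell types, sex and clock. They were tested with camera at a preset inter-gene correlation of 0.01, adjusted over lists within a comparison, and again with that correlation estimated. The list of mitochondrially encoded subunits had no member in the table used here. A list score is the mean over a list's genes of the log2 deviation from the mean of all 14 libraries. Genes named in the text were chosen by a rule also written beforehand. It took the 6 largest increases and 6 largest decreases of each main comparison among called genes with a mean log2 value of at least 1 and no overlap between the groups. It also took up to 2 called members in each direction of each list, or the 2 with the highest mean where none was called. Hif1a, Rarb, Stra6, Lrat, Dhrs3, Atf4, Atf5, Ddit3, Hspd1, Lonp1 and Clpp were named in any case. Some genes that the rule takes are not reported here. Alternatives were median-ratio scaling, no filter, pseudocounts of 0.1 and 5, the replicate number or the lane as a term, only the groups compared in the fit, and each library left out in turn. Values as deposited without scaling, a filter at 5 FPKM, keeping the genes with values listed at 0, and leaving out TRACK-VAD libraries 1 and 2 were added after the data were seen.

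In simulated values for 12251 genes, 200 were changed by log2 0.5, 1, 2 or 3. Shares recovered (%) were 44, 88, 98 and 100 for TRACK against WT and 52, 90, 98 and 100 for TRACK-VAD against WT-VAD. They were 40, 90, 100 and 100 for WT-VAD against WT and 58, 92, 94 and 100 for TRACK-VAD against TRACK. The interaction had 22, 72, 92 and 100. False calls were 4.62%, 1.73%, 7.82%, 6.52% and 2.72% of calls in this order. These shares may not hold for TRACK-VAD, whose libraries spread more.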

Results

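Gene expression was measured in kidney cortex of wild-type mice and of TRACK mice, a transgenic line in which HIF1A, the oxygen-regulated subunit of the hypoxia-inducible transcription factor, is constitutively active. Mice of both genotypes ate regular chow or a vitamin A deficient diet, which gave 3 WT, 4 TRACK, 3 WT-VAD and 4 TRACK-VAD libraries. The series title places the work on kidney cancer of the clear cell type and on stress responses of mitochondria, and the design asks how the transgene and the diet change kidney expression. Values are deposited FPKM, so the absolute depth is unknown. Relative to the mean of all libraries, depth was 0.937 to 1.27 in WT, 0.923 to 1.29 in TRACK, 0.839 to 1.07 in WT-VAD and 0.82 to 1.03 in TRACK-VAD. Across the 12251 genes tested, the Pearson correlation between libraries of a group was 0.957 to 0.991 in TRACK-VAD and 0.988 to 0.992 in the other groups; genes are not independent replicates.

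Mouse Hif1a (ENSMUSG00000021109, chromosome 12, 73901375 to 73947530) was measured first, since the transgene concerns this factor. Its deposited values lay between 20.6 and 32.3 FPKM over all 14 libraries. Scaled means were 29.1 ± 1.79 FPKM (SD, n = 3) in WT, 27.8 ± 3.02 FPKM (SD, n = 4) in TRACK, 27.4 ± 4.85 FPKM (SD, n = 3) in WT-VAD and 25.9 ± 4.05 FPKM (SD, n = 4) in TRACK-VAD. The log2 difference between genotypes was -0.07 ± 0.13 (SE) on chow (adjusted p = 0.766) and -0.08 ± 0.13 on the deficient diet (adjusted p = 0.707), both within the spread between libraries. Both differences turned positive without scaling, at 0.10 and 0.12, and remained uncalled. A separate row for the transgene was not analysed here, so these values do not check the genotype labels. The score of the HIF target list was above 0 in all 8 transgenic and below 0 in all 6 wild-type libraries.

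The largest increase in TRACK over WT kidneys on chow, among genes with no overlap between the groups, was in 2610528A11Rik (ENSMUSG00000096001, chromosome 14, 37102140 to 37114022), which rose from 0.123 ± 0.0562 FPKM (SD, n = 3) to 163 ± 22.4 FPKM (SD, n = 4) (log2 fold change 7.18 ± 0.21 (SE), adjusted p = 2.03e-10). Igfbp2, which encodes a binding protein for insulin-like growth factors, rose from 0.718 ± 0.504 FPKM to 127 ± 28.8 FPKM (log2 fold change 6.23 ± 0.37 (SE), adjusted p = 1.91e-07). Ndufa4l2, a mitochondrial protein gene induced by HIF, rose from 2.46 ± 0.0574 FPKM to 128 ± 8.57 FPKM (log2 fold change 5.22 ± 0.19 (SE), adjusted p = 2.18e-09). Genes of plasma proteins known from liver and intestine also rose, namely the apolipoprotein genes Apoc3 (5.60, adjusted p = 5.41e-07) and Apoa4 (5.29, adjusted p = 3.84e-06) and the prothrombin gene F2 (5.36, adjusted p = 6.69e-08). The largest decrease was in Hpd, an enzyme of tyrosine breakdown, from 146 ± 26.6 FPKM to 8.06 ± 4.14 FPKM (log2 fold change -4.15 ± 0.50 (SE), adjusted p = 0.000121). Decreases followed in Azgp1 (-2.61, adjusted p = 0.000253), Wdfy1 (-2.34, adjusted p = 9.46e-08), Anxa13 (-2.26, adjusted p = 4.91e-06), the alanine aminotransferase gene Gpt (-2.09, adjusted p = 0.00063) and Cyp2e1 (-2.02, adjusted p = 0.000852), a cytochrome P450 that fell from 1909.8 ± 389 FPKM to 475 ± 129 FPKM. In the table (GRCm38 loci), Igfbp2 lies at chromosome 1, 72824503 to 72852474, Ndufa4l2 at chromosome 10, 127514939 to 127517152, Hpd at chromosome 5, 123171807 to 123182727, and Cyp2e1 at chromosome 7, 140763739 to 140774987.

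Limma called 2087 of 12251 genes between TRACK and WT at an adjusted p of 0.05 or less, 1082 higher and 1005 lower (51.8% higher). At least a doubling or the inverse was seen in 221 higher and 78 lower genes. All 7 libraries share lane 5. As deposited, without scaling, 2264 genes were called and 80.3% of them were higher, since the median gene then shifts by 0.16 (log2); changes below are relative to that shift. The count was 3377 with only these groups in the fit, and fell to 1004 without WT 1, 1017 without WT 3, 1336 without TRACK 2 and 1248 without TRACK 3.

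**Figure D1:**
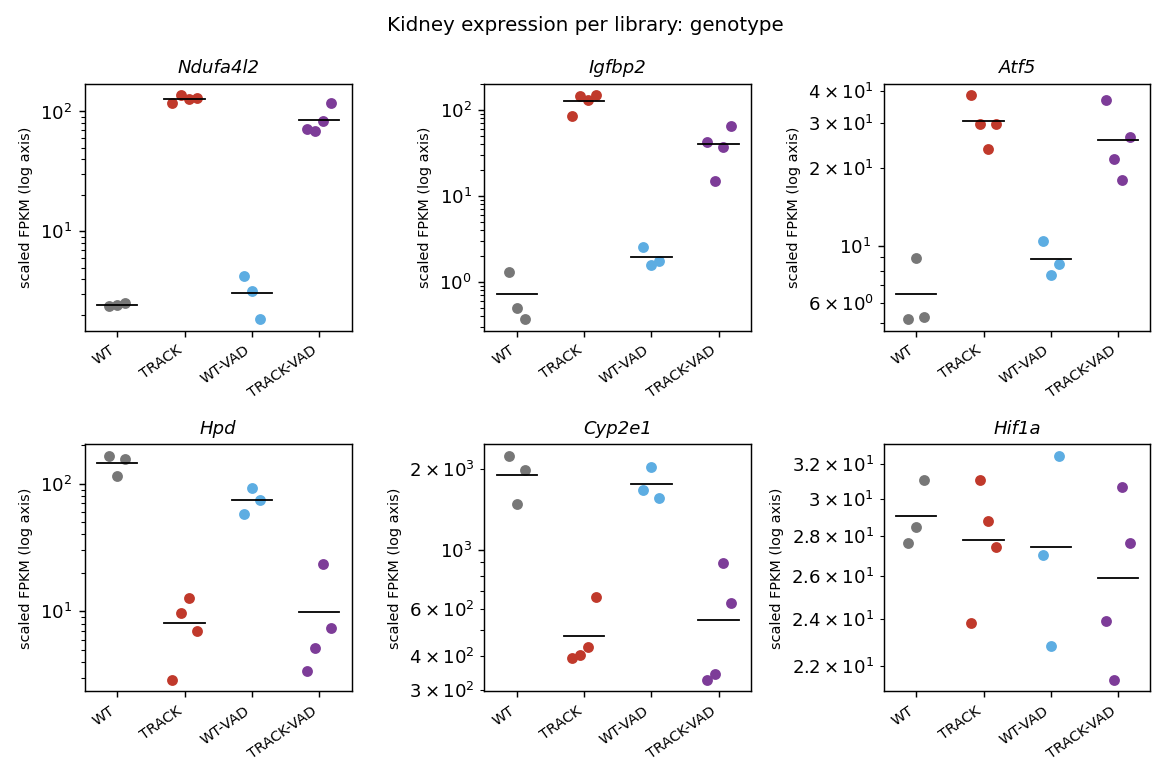
Scaled FPKM (log axis) of 6 genes in each library, grouped as WT, TRACK, WT-VAD and TRACK-VAD; points are libraries and lines are group means. Ndufa4l2, Igfbp2 and Atf5 were higher and Hpd and Cyp2e1 lower in every transgenic library than in every wild-type library of the same diet, while Hif1a lay between 21.4 and 32.5 FPKM throughout.

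In energy metabolism on chow, genes of glycolysis were higher and genes of fatty acid oxidation lower in TRACK kidneys. Proximal tubule genes were lower too (list median -0.78), so a change in cell composition was not separated from these changes or those of mitochondrial genes. Of the 19 glycolysis genes, 15 rose, or 17 adjusted over the list alone. The lactate exporter gene Slc16a3 rose by 4.36 ± 0.17 (log2, SE) and the phosphofructokinase gene Pfkp by 3.29 ± 0.16. For glycolysis genes camera pointed up (adjusted p = 9.15e-20, 0.0848 with estimated correlation). Of the 29 other HIF target genes, 21 rose and 2 fell, or 22 and 2 adjusted over the list alone. For other HIF target genes camera pointed up (adjusted p = 3.27e-16, 0.0369 with estimated correlation). This was the one list whose call held with an estimated correlation. Ankrd37 (3.53, adjusted p = 4.85e-07) rose, whereas Ndrg1 (-0.65, adjusted p = 0.00474) and the monocarboxylate transporter gene Slc16a1 (-0.40, adjusted p = 0.0451) fell. Of the 24 fatty acid oxidation genes, 16 fell, or 19 adjusted over the list alone, and 10 without scaling, including the peroxisomal gene Acaa1b (-1.45, adjusted p = 9.31e-05). For fatty acid oxidation genes camera pointed down (adjusted p = 4.34e-11, 0.0848 with estimated correlation). Of the 20 TCA cycle genes, 7 fell, or 15 adjusted over the list alone, and 1 higher and 2 lower without scaling, with Dlst (-0.50, adjusted p = 0.0104) and Suclg2 (-0.44, adjusted p = 0.0027) among them. The median was -0.31, or -0.13 without scaling. For TCA cycle genes camera pointed down (adjusted p = 1.16e-06, 0.392 with estimated correlation). Of the 20 lipid and cholesterol synthesis genes, 5 rose and 2 fell, or 5 and 2 adjusted over the list alone, with Sqle (0.78, adjusted p = 0.000659) higher and Insig1 (-0.55, adjusted p = 0.0418) lower. For lipid and cholesterol synthesis genes camera pointed up (adjusted p = 0.623). Of the 9 gluconeogenesis genes, 2 rose, or 2 adjusted over the list alone, among them Pck2 (0.94, adjusted p = 0.00178). For gluconeogenesis genes camera pointed up (adjusted p = 0.512). Slc16a1 (0.057 to 0.121 without WT 1, 2 or 3 or TRACK 1, 2, 3 or 4), Dlst (0.0547 without WT 3) and Insig1 (0.0505 to 0.136 without WT 1, 2 or 3 or TRACK 1, 2, 3 or 4) lost their calls without 1 library (adjusted p). Without scaling Slc16a1 and Insig1 were not called.

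Medians of nuclear mitochondrial lists lay just below the median gene after scaling, with few members called. Of the 36 complex I genes, 6 fell, or 6 adjusted over the list alone, and 0 without scaling, among them Ndufs1 (-0.44, adjusted p = 0.0364) and Ndufa10 (-0.35, adjusted p = 0.0469). For complex I genes camera pointed down (adjusted p = 5.69e-05, 0.467 with estimated correlation). Of the 34 complex III to V genes, 4 fell, or 3 adjusted over the list alone, and 1 without scaling, with Atp5b (-0.43, adjusted p = 0.0228) and Uqcrfs1 (-0.40, adjusted p = 0.0197). For complex III to V genes camera pointed down (adjusted p = 2.49e-05, 0.461 with estimated correlation). Of the 40 mitochondrial ribosome genes, 4 fell, or 4 adjusted over the list alone, and 0 without scaling, with Mrps22 (-0.39, adjusted p = 0.0208) and Mrpl16 (-0.36, adjusted p = 0.0087). For mitochondrial ribosome genes camera pointed down (adjusted p = 0.000223, 0.461 with estimated correlation). Of the 20 mitochondrial biogenesis and dynamics genes, 2 fell, or 2 adjusted over the list alone, and 0 without scaling, namely Pink1 (-0.36, adjusted p = 0.0144) and Tfam (-0.31, adjusted p = 0.0174). For mitochondrial biogenesis and dynamics genes camera pointed down (adjusted p = 0.0214, 0.392 with estimated correlation). Of the 16 mitochondrial chaperone and protease genes, 3 fell, or 3 adjusted over the list alone, and 2 higher and 1 lower without scaling. The protease subunit gene Clpx (-0.69, adjusted p = 0.00744) and the chaperonin gene Hspd1 (-0.45, adjusted p = 0.0123) fell, while the protease genes Lonp1 (0.27, adjusted p = 0.0919) and Clpp (-0.23, adjusted p = 0.0714) were not called. For mitochondrial chaperone and protease genes camera pointed down (adjusted p = 0.0113, 0.392 with estimated correlation). The list medians lay at -0.18 to -0.15 (log2) after scaling but at 0.00 to 0.02 in the values as deposited. Relative to other genes camera still pointed down without scaling, with adjusted p of 0.00951, 0.00106, 0.0447, 0.0381 and 0.126. Without scaling, Ndufs1, Ndufa10, Atp5b, Mrps22, Mrpl16, Pink1, Tfam and Hspd1 were not called. Ndufs1 (0.0595 to 0.12 without WT 1, 2 or 3 or TRACK 1, 2, 3 or 4), Ndufa10 (0.0604 to 0.187 without WT 1 or 3 or TRACK 1, 2, 3 or 4), Atp5b (0.0608 to 0.0944 without WT 1 or 3 or TRACK 2 or 3), Uqcrfs1 (0.0542 to 0.0856 without WT 1 or 3 or TRACK 3) and Mrps22 (0.0625 to 0.0894 without WT 1 or 2 or TRACK 3) lost their calls without 1 library (adjusted p). Mrpl16 (0.0538 without WT 1), Pink1 (0.0732 to 0.0756 without WT 1 or 3) and Tfam (0.061 to 0.0752 without WT 1 or 3) lost their calls in the same way.

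Genes of the integrated stress response, the programme driven by ATF4 when translation initiation is limited, were higher in TRACK kidneys on chow. Of the 22 integrated stress response genes, 11 rose and 1 fell, or 15 and 1 adjusted over the list alone. For integrated stress response genes camera pointed up (adjusted p = 3.56e-06, 0.36 with estimated correlation). The transcription factor genes Atf5 (2.09, adjusted p = 6.06e-05), Ddit3 (1.27, adjusted p = 0.0013) and Atf4 (0.82, adjusted p = 0.00707) rose, as did Trib3 (2.81, adjusted p = 4.26e-06) and the asparagine synthetase gene Asns (2.40, adjusted p = 0.00115), whereas Sesn2 (-1.03, adjusted p = 0.000454) fell. Atf5 went from 6.46 ± 2.14 FPKM to 30.5 ± 6.12 FPKM. Of the 18 serine and folate-cycle genes, 6 rose and 2 fell, or 7 and 3 adjusted over the list alone, and 7 and 0 without scaling. Aldh1l2 (3.85, adjusted p = 2.49e-06) rose, and so did Aldh18a1 (3.51, adjusted p = 1.96e-07), which is on this list but belongs to neither pathway. The cytosolic enzymes Aldh1l1 (-0.63, adjusted p = 0.0442) and Shmt1 (-0.32, adjusted p = 0.0245) fell. For serine and folate-cycle genes camera pointed up (adjusted p = 0.225). Of the 17 endoplasmic reticulum chaperone genes, 2 rose, or 2 adjusted over the list alone, and 8 without scaling, namely Sdf2l1 (0.81, adjusted p = 0.0152) and Pdia6 (0.59, adjusted p = 0.00346). Without scaling camera pointed up at an adjusted p of 0.0121. For endoplasmic reticulum chaperone genes camera pointed up (adjusted p = 0.0901). Of the 16 NRF2 target genes, 4 fell, or 1 higher and 4 lower adjusted over the list alone, and 2 higher and 1 lower without scaling, with Gsr (-0.69, adjusted p = 0.00474) and Gsta3 (-0.62, adjusted p = 0.00601) lower. For NRF2 target genes camera pointed down (adjusted p = 0.181). Aldh1l1 (0.0593 to 0.143 without WT 1, 2 or 3 or TRACK 1, 2, 3 or 4), Shmt1 (0.0507 to 0.128 without WT 1 or 3 or TRACK 1, 2 or 3) and Sdf2l1 (0.0629 without WT 3) lost their calls without 1 library (adjusted p). Without scaling Aldh1l1, Shmt1 and Gsta3 were not called.

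Proximal tubule genes were lower, and injury, immune and endothelial genes higher, in TRACK kidneys on chow. Of the 25 proximal tubule genes, 11 fell, or 14 adjusted over the list alone, among them Slc22a8 (-1.46, adjusted p = 0.00296) and Cyp2e1. For proximal tubule genes camera pointed down (adjusted p = 6.54e-08, 0.392 with estimated correlation). Of the 16 tubular injury genes, 9 rose, or 12 adjusted over the list alone. Havcr1, the gene of kidney injury molecule KIM-1, rose from 0.778 ± 0.0726 FPKM to 35.1 ± 14.7 FPKM (log2 fold change 4.24 ± 0.70 (SE), adjusted p = 0.00138), and the cell cycle inhibitor gene Cdkn1a (2.25, adjusted p = 5.82e-05) rose. For tubular injury genes camera pointed up (adjusted p = 4.96e-06, 0.392 with estimated correlation). Of the 19 macrophage and dendritic cell genes, 17 rose, or 17 adjusted over the list alone, with the lysozyme gene Lyz2 (1.38, adjusted p = 0.0111) and the MHC class II gene H2-Ab1 (1.31, adjusted p = 0.00501). For macrophage and dendritic cell genes camera pointed up (adjusted p = 1.55e-09, 0.36 with estimated correlation). Of the 20 interferon response genes, 14 rose, or 17 adjusted over the list alone, with Cxcl10 (1.49, adjusted p = 0.00172). For interferon response genes camera pointed up (adjusted p = 1.19e-07, 0.361 with estimated correlation). Of the 11 lymphocyte genes, 6 rose, or 8 adjusted over the list alone, with Jchain (4.15, adjusted p = 0.000102) and the chemokine gene Ccl5 (1.34, adjusted p = 0.048). For lymphocyte genes camera pointed up (adjusted p = 4.76e-05, 0.36 with estimated correlation). Of the 14 endothelial cell genes, 8 rose, or 10 adjusted over the list alone, with Esam (0.78, adjusted p = 0.000212) and Robo4 (0.66, adjusted p = 0.00573). For endothelial cell genes camera pointed up (adjusted p = 6.43e-07, 0.0848 with estimated correlation). Of the 16 fibroblast and matrix genes, 4 rose, or 5 adjusted over the list alone, with the fibronectin gene Fn1 (1.58, adjusted p = 0.000372). For fibroblast and matrix genes camera pointed up (adjusted p = 0.000305, 0.392 with estimated correlation). Of the 18 loop of Henle and distal tubule genes, 1 rose, or 0 adjusted over the list alone, the risen gene being Ptger3 (0.42, adjusted p = 0.0299). For loop of Henle and distal tubule genes camera pointed down (adjusted p = 0.678). Of the 16 collecting duct genes, none passed limma's test, also adjusted over the list alone, and 3 higher and 1 lower had an unadjusted p at or under 0.05, and 2 higher and 0 lower without scaling, Aqp3 at -0.28 and Hsd11b2 at -0.19. For collecting duct genes camera pointed up (adjusted p = 0.655). Of the 10 podocyte genes, none passed limma's test, also adjusted over the list alone, and 0 higher and 0 lower had an unadjusted p at or under 0.05, Podxl at 0.18. For podocyte genes camera pointed up (adjusted p = 0.655). Lyz2 (0.0643 without WT 3), Ccl5 (0.065 to 0.175 without WT 1, 2 or 3 or TRACK 1, 2 or 3) and Ptger3 (0.0593 to 0.099 without WT 1, 2 or 3 or TRACK 2 or 3) lost their calls without 1 library (adjusted p).

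Retinoid genes went both ways on chow. Of the 22 retinoid genes, 4 rose and 6 fell, or 5 and 6 adjusted over the list alone, and 5 and 3 without scaling. For retinoid genes camera pointed down (adjusted p = 0.655). The retinol carrier gene Rbp4 (3.35, adjusted p = 3.88e-05) rose from 3.68 ± 2.06 FPKM to 43.7 ± 3.41 FPKM, and the retinoic acid receptor gene Rarg (0.81, adjusted p = 0.0444) rose, the latter by 0.49 without TRACK 2, while Bco2 (-0.68, adjusted p = 0.0156), Tgm2 (-0.61, adjusted p = 0.00667), Dhrs3 (-0.60, adjusted p = 0.00131) and Lrat (-0.41, adjusted p = 0.0366) fell. Rarb (0.23, adjusted p = 0.0886) and Stra6 (-0.40, adjusted p = 0.575) were not called. Of the 14 cell cycle genes, 5 rose, or 5 adjusted over the list alone, including Cdk1 (1.41, adjusted p = 0.00531) and Top2a (0.64, adjusted p = 0.0305). For cell cycle genes camera pointed up (adjusted p = 0.00134, 0.36 with estimated correlation). Of the 18 immediate early genes, 6 rose, or 6 adjusted over the list alone, including Atf3 (1.28, adjusted p = 0.0037) and Btg2 (1.25, adjusted p = 0.00255). For immediate early genes camera pointed up (adjusted p = 0.000121, 0.392 with estimated correlation). Of the 17 circadian clock genes, 1 rose, or 0 adjusted over the list alone, and 3 without scaling, the risen gene being Dbp (0.82, adjusted p = 0.0381). For circadian clock genes camera pointed up (adjusted p = 0.605). Of the 15 male-biased kidney genes, 4 fell, or 1 higher and 5 lower adjusted over the list alone, and 1 higher and 3 lower without scaling, with Cyp2d9 (-1.73, adjusted p = 0.000377) and Cyp4b1 (-1.61, adjusted p = 0.0010). The labels do not give the sex of the mice. For male-biased kidney genes camera pointed down (adjusted p = 0.0151, 0.467 with estimated correlation). Of the 12 female-biased kidney genes, 2 rose and 5 fell, or 2 and 5 adjusted over the list alone, with Slc7a12 (2.02, adjusted p = 0.000452) and Abcc3 (0.75, adjusted p = 0.0345) higher and Cyp2a5 (-1.98, adjusted p = 0.000175) and Cyp2d12 (-1.76, adjusted p = 0.0259) lower. Without scaling camera called the list (adjusted p = 0.00272). For female-biased kidney genes camera pointed down (adjusted p = 0.0901). Of the 3 perirenal fat and adrenal genes, none passed limma's test over all genes, 2 higher and 0 lower did adjusted over the list alone, and 2 higher and 0 lower had an unadjusted p at or under 0.05. TRACK library 4 had a score of 4.48 against -0.30 to -0.20 in the other TRACK libraries, and without it 1601 genes were called between TRACK and WT. For perirenal fat and adrenal genes camera pointed up (adjusted p = 0.178). Of the 6 muscle and blood genes, none passed limma's test, also adjusted over the list alone, and 1 higher and 0 lower had an unadjusted p at or under 0.05, and 1 higher and 0 lower without scaling, Hba-a1 at -0.49 and Hba-a2 at -0.55. For muscle and blood genes camera pointed up (adjusted p = 0.886). Among all lists, median, mean and camera direction differed in sign for gluconeogenesis, serine and one-carbon metabolism, lipid and cholesterol synthesis, retinoid signalling and storage, collecting duct, circadian clock and muscle and blood; beside the mitochondrial lists other than complexes III to V, the median turned positive without scaling for gluconeogenesis, serine and one-carbon metabolism, lipid and cholesterol synthesis, NRF2 targets, retinoid signalling and storage, loop of Henle and distal tubule, collecting duct, circadian clock and muscle and blood. Top2a (0.0856 to 0.121 without WT 1 or 3), Dbp (0.0604 to 0.141 without WT 1 or 2 or TRACK 2, 3 or 4), Abcc3 (0.0628 to 0.115 without WT 1, 2 or 3 or TRACK 1, 2 or 3), Cyp2d12 (0.0525 to 0.113 without WT 1 or 3 or TRACK 2 or 3) and Rarg (0.057 to 0.134 without WT 1, 2 or 3 or TRACK 4) lost their calls without 1 library (adjusted p). Bco2 (0.0629 to 0.0632 without WT 1 or 3) and Lrat (0.10 to 0.121 without WT 1 or 2 or TRACK 2 or 3) lost their calls in the same way. Without scaling Tgm2 and Lrat were not called.

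**Figure D2:**
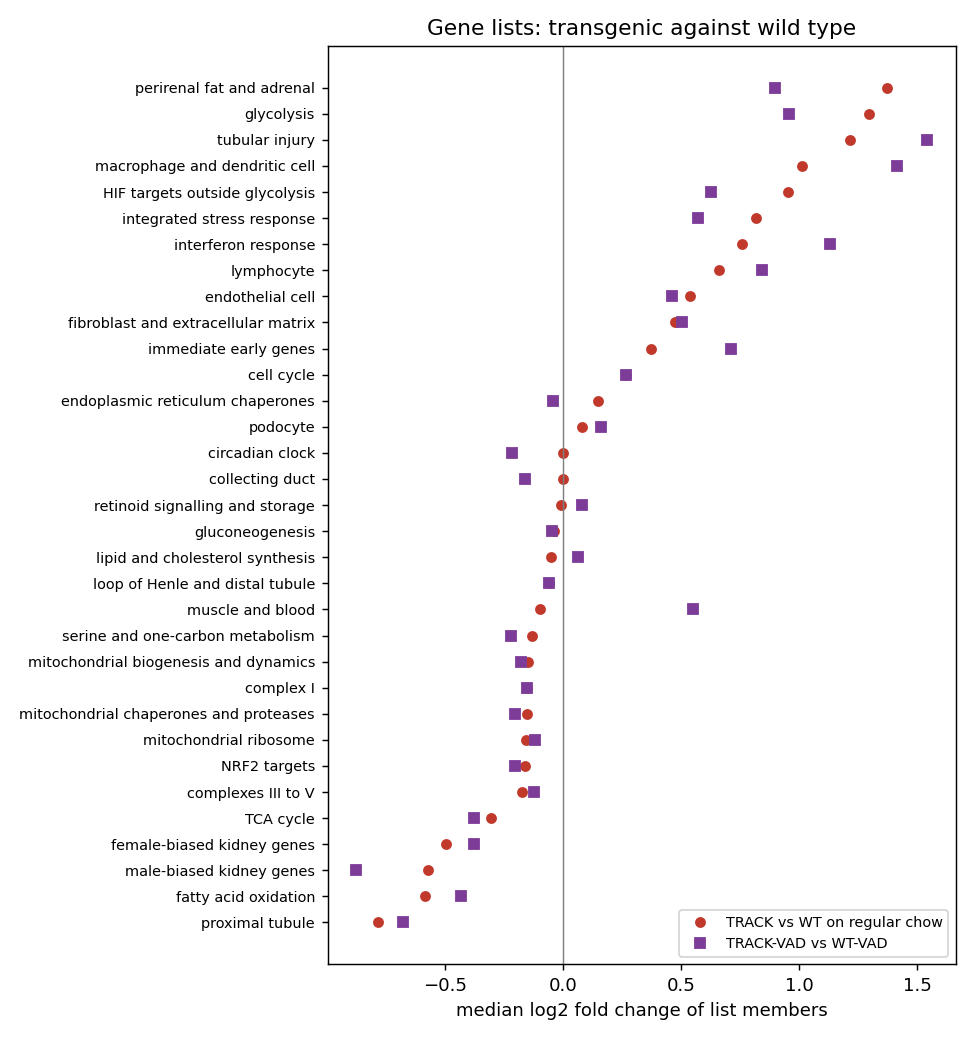
Median log2 fold change of the members of each gene list for TRACK against WT on chow (circles) and TRACK-VAD against WT-VAD (squares), after scaling. Glycolysis lay at 1.30 and 0.95 and proximal tubule at -0.78 and -0.68.

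On the deficient diet, TRACK-VAD kidneys were compared with WT-VAD kidneys to ask what the transgene changes without dietary vitamin A. 2610528A11Rik was again the largest increase, from 0.40 ± 0.245 FPKM (SD, n = 3) to 80.9 ± 26.6 FPKM (SD, n = 4) (log2 fold change 5.83 ± 0.21 (SE), adjusted p = 3.15e-09). Havcr1 rose from 2.16 ± 0.978 FPKM to 127 ± 128 FPKM (log2 fold change 4.70 ± 0.70 (SE), adjusted p = 0.000886), and Ndufa4l2 from 3.1 ± 1.21 FPKM to 85.3 ± 22.8 FPKM (log2 fold change 4.41 ± 0.19 (SE), adjusted p = 1.69e-08). Apoc3 (4.37, adjusted p = 1.09e-05), Defb19 (4.19, adjusted p = 1.69e-08) and Ankrd37 (3.68, adjusted p = 4.04e-07) followed. The largest decreases were in Pzp (-3.19, adjusted p = 0.0103), Hpd (-3.10, adjusted p = 0.00156), the cytochrome P450 genes Cyp4a12a (-3.09, adjusted p = 0.00895) and Cyp2a5 (-2.41, adjusted p = 6.07e-05), Ctxn3 (-2.99, adjusted p = 0.000112) and Wdfy1 (-2.30, adjusted p = 1.71e-07). Limma called 2707 genes, 1380 higher and 1327 lower (51% higher, but 82.7% of 3218 without scaling, where the median gene shifts by 0.18), with 276 higher and 121 lower by at least a factor of 2. All WT-VAD libraries are in lane 6 with 1 of 4 TRACK-VAD libraries, too few for a value within the lane. With lane as a term, TRACK-VAD 4 alone is compared with the WT-VAD mean, here and below, so these values rest on 1 library. They were 3.95 for Havcr1, -1.63 for Pzp, -3.16 for Hpd and -1.56 for Cyp4a12a (log2). The count was 1277 without TRACK-VAD 1 and 2 (Pzp then -1.56 and Cyp4a12a -1.55), 576 with these groups alone, 1737 without TRACK-VAD 1, and 1636, 1569 and 1638 without WT-VAD 1, 2 and 3.

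Gene groups were tested the same way on this diet, and no list kept its call with an estimated correlation. Of the 19 glycolysis genes, 15 rose and 1 fell, or 17 and 1 adjusted over the list alone, and 18 and 0 without scaling. Slc16a3 rose by 3.52 ± 0.17 (log2, SE) and Pfkp by 2.65 ± 0.16, while Pfkm (-0.48, adjusted p = 0.0427) fell, with -0.30 without TRACK-VAD 2. For glycolysis genes camera pointed up (adjusted p = 1.40e-15, 0.124 with estimated correlation). Of the 29 other HIF target genes, 17 rose and 1 fell, or 20 and 1 adjusted over the list alone, Car12 (-0.70, adjusted p = 0.0306) being the gene that fell. For other HIF target genes camera pointed up (adjusted p = 1.66e-13, 0.0708 with estimated correlation). Of the 24 fatty acid oxidation genes, 16 fell, or 18 adjusted over the list alone, and 8 without scaling, with Acaa1b (-1.35, adjusted p = 0.000253) and Ehhadh (-1.17, adjusted p = 4.84e-05). For fatty acid oxidation genes camera pointed down (adjusted p = 7.14e-09, 0.165 with estimated correlation). Of the 20 TCA cycle genes, 12 fell, or 16 adjusted over the list alone, and 5 without scaling, with Dlst (-0.56, adjusted p = 0.00625) and Sucla2 (-0.50, adjusted p = 0.00773). For TCA cycle genes camera pointed down (adjusted p = 1.94e-07, 0.318 with estimated correlation). Of the 22 integrated stress response genes, 14 rose, or 14 adjusted over the list alone. Trib3 (2.25, adjusted p = 6.07e-05), Nupr1 (1.70, adjusted p = 0.00739), Atf5 (1.40, adjusted p = 0.00178), Ddit3 (0.98, adjusted p = 0.00685) and Atf4 (0.57, adjusted p = 0.0361) rose, Atf4 by 0.37 without WT-VAD 1. For integrated stress response genes camera pointed up (adjusted p = 1.33e-06, 0.257 with estimated correlation). Of the 16 mitochondrial chaperone and protease genes, 7 fell, or 7 adjusted over the list alone, and 1 higher and 2 lower without scaling, with Hspd1 (-0.74, adjusted p = 0.000675) and Timm23 (-0.57, adjusted p = 0.0379). Lonp1 (0.05, adjusted p = 0.762) and Clpp (-0.15, adjusted p = 0.213, positive without scaling) were not called. For mitochondrial chaperone and protease genes camera pointed down (adjusted p = 0.000315, 0.282 with estimated correlation). Of the 36 complex I genes, 3 fell, or 3 adjusted over the list alone, and 2 higher and 2 lower without scaling. Camera pointed down (adjusted p = 0.00172, 0.624 with estimated correlation). Of the 34 complex III to V genes, 3 fell, or 2 adjusted over the list alone, and 1 higher and 1 lower without scaling. Camera pointed down (adjusted p = 0.0195, 0.669 with estimated correlation). Of the 40 mitochondrial ribosome genes, 6 fell, or 2 adjusted over the list alone, and 1 higher and 0 lower without scaling. Camera pointed down (adjusted p = 0.00521, 0.562 with estimated correlation). Of the 20 mitochondrial biogenesis and dynamics genes, 3 fell, or 3 adjusted over the list alone, and 2 higher and 1 lower without scaling. Camera pointed down (adjusted p = 0.0271, 0.318 with estimated correlation). The medians of these 5 mitochondrial lists lay at -0.20 to -0.12 with scaling and 0.01 to 0.09 without, where camera pointed down at adjusted p of 0.346, 0.425, 0.498, 0.0982 and 0.0104 in the order of the chow lists. Pfkm (0.0745 to 0.114 without TRACK-VAD 1 or WT-VAD 1, 2 or 3), Car12 (0.0703 to 0.0871 without TRACK-VAD 1 or WT-VAD 1, 2 or 3), Timm23 (0.0599 to 0.134 without TRACK-VAD 1, 2 or 3 or WT-VAD 1, 2 or 3) and Atf4 (0.0903 to 0.164 without TRACK-VAD 1 or 2 or WT-VAD 1 or 3) lost their calls without 1 library (adjusted p). The lane term ended the calls of Pfkm (-0.25), Car12 (-0.29), Dlst (-0.36), Sucla2 (-0.40), Hspd1 (-0.66), Timm23 (-0.27), Nupr1 (0.93), Atf5 (1.49), Ddit3 (0.81) and Atf4 (0.34), given as log2 with lane. Without scaling Pfkm and Timm23 were not called. TRACK-VAD libraries 1 to 4 had TCA cycle scores of -0.22, -0.44, 0.00 and -0.08 and stress response scores of 0.64, 0.44, -0.03 and 0.22; without libraries 1 and 2, Pfkm, Car12, Timm23 and Atf4 were not called.

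Injury and immune genes were higher and proximal tubule genes lower in TRACK-VAD than in WT-VAD kidneys. Of the 16 tubular injury genes, 13 rose, or 14 adjusted over the list alone, with Havcr1 and Krt20 (2.40, adjusted p = 0.0102). For tubular injury genes camera pointed up (adjusted p = 7.14e-09, 0.282 with estimated correlation). Of the 19 macrophage and dendritic cell genes, 18 rose, or 18 adjusted over the list alone, with Cd14 (2.04, adjusted p = 0.0119) and H2-Ab1 (1.83, adjusted p = 0.000687). Camera pointed up (adjusted p = 1.66e-13, 0.213 with estimated correlation). Of the 20 interferon response genes, 17 rose, or 19 adjusted over the list alone, with Cxcl10 (1.71, adjusted p = 0.000886) and Gbp2 (1.62, adjusted p = 0.0091). Camera pointed up (adjusted p = 2.14e-13, 0.213 with estimated correlation). Of the 11 lymphocyte genes, 9 rose, or 11 adjusted over the list alone, with Ccl5 (2.06, adjusted p = 0.00643) and Jchain (1.93, adjusted p = 0.0154). For lymphocyte genes camera pointed up (adjusted p = 2.33e-06, 0.213 with estimated correlation). Of the 14 endothelial cell genes, 9 rose, or 11 adjusted over the list alone, with Emcn (0.98, adjusted p = 0.000861) and Pecam1 (0.76, adjusted p = 0.00435). For endothelial cell genes camera pointed up (adjusted p = 1.38e-06, 0.124 with estimated correlation). Of the 16 fibroblast and matrix genes, 6 rose, or 8 adjusted over the list alone, with Fn1 at 1.21 and Vim (1.09, adjusted p = 0.0153). Camera pointed up (adjusted p = 8.62e-05, 0.318 with estimated correlation). Of the 25 proximal tubule genes, 12 fell, or 16 adjusted over the list alone, with Slc22a6 (-1.94, adjusted p = 0.000467) and Cyp2e1 (-1.81, adjusted p = 0.00234). For proximal tubule genes camera pointed down (adjusted p = 1.21e-08, 0.318 with estimated correlation). The 4 TRACK-VAD libraries were far apart in these groups: the injury scores of libraries 1 to 4 were 0.93, 2.00, 0.10 and 0.30, the macrophage scores 0.52, 1.59, 0.41 and 0.50 and the proximal tubule scores -0.73, -1.25, 0.04 and 0.00, against -0.84 to -0.75, -0.69 to -0.41 and 0.31 to 0.48 in WT-VAD. Jchain (0.0503 to 0.0654 without WT-VAD 1 or 3) and Vim (0.0538 to 0.060 without WT-VAD 2 or 3) lost their calls without 1 library (adjusted p). The lane term ended the calls of Slc22a6 (-1.37), Cyp2e1 (-1.47), Krt20 (1.61), Cd14 (1.15), H2-Ab1 (1.48), Cxcl10 (1.18), Gbp2 (1.02), Ccl5 (1.26), Emcn (0.71), Pecam1 (0.69) and Vim (0.61), given as log2 with lane.

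Retinoid genes on the deficient diet went both ways. Of the 22 retinoid genes, 1 rose and 2 fell, or 1 and 2 adjusted over the list alone, and 5 and 1 without scaling, Bco2 (-1.03, adjusted p = 0.00185) and Dhrs3 (-0.39, adjusted p = 0.0147) lower. Rarb (0.16), Stra6 (0.81, negative with lane as a term) and Lrat (-0.31) had adjusted p of 0.219, 0.204 and 0.0838. For retinoid genes camera pointed up (adjusted p = 0.724). Of the 18 immediate early genes, 9 rose, or 10 adjusted over the list alone, with Atf3 (1.27, adjusted p = 0.00419) and Btg2 (1.22, adjusted p = 0.00327). For immediate early genes camera pointed up (adjusted p = 5.71e-06, 0.318 with estimated correlation). Of the 14 cell cycle genes, 2 rose, or 2 adjusted over the list alone, and 8 without scaling, among them Ccnb2 (0.65, adjusted p = 0.0141). Without scaling camera's adjusted p was 0.14. For cell cycle genes camera pointed up (adjusted p = 0.0227, 0.366 with estimated correlation). Of the 17 circadian clock genes, 3 rose and 2 fell, or 3 and 3 adjusted over the list alone, and 4 and 0 without scaling, with Arntl (0.76, adjusted p = 0.0163) higher and Nr1d2 (-0.32, adjusted p = 0.0295) lower. For circadian clock genes camera pointed down (adjusted p = 0.626). Of the 15 male-biased kidney genes, 8 fell, or 8 adjusted over the list alone, with Cyp4a12a and Slco1a1 (-1.72, adjusted p = 0.0385), the latter at -1.06 without TRACK-VAD 2. For male-biased kidney genes camera pointed down (adjusted p = 7.02e-05, 0.318 with estimated correlation). Of the 12 female-biased kidney genes, 1 rose and 3 fell, or 1 and 3 adjusted over the list alone, Slc7a12 (2.57, adjusted p = 0.000116) being higher and Cyp2a4 (-0.88, adjusted p = 0.00156) and Cyp2a5 lower. Without scaling camera's adjusted p was 0.0104. For female-biased kidney genes camera pointed down (adjusted p = 0.22). Of the 20 lipid and cholesterol synthesis genes, 5 rose and 1 fell, or 5 and 1 adjusted over the list alone, with Fasn (0.68, adjusted p = 0.0198) and Acly (0.65, adjusted p = 0.00168) higher. For lipid and cholesterol synthesis genes camera pointed up (adjusted p = 0.223). Median, mean and camera direction differed in sign for serine and one-carbon metabolism and endoplasmic reticulum chaperones; beside the mitochondrial lists, the median turned positive without scaling for gluconeogenesis, endoplasmic reticulum chaperones, NRF2 targets, loop of Henle and distal tubule and collecting duct. Slco1a1 (0.0821 to 0.104 without TRACK-VAD 1 or WT-VAD 1, 2 or 3), Dhrs3 (0.0648 without WT-VAD 1), Arntl (0.0594 to 0.0687 without WT-VAD 2 or 3), Nr1d2 (0.0553 to 0.126 without TRACK-VAD 1 or 2 or WT-VAD 1 or 3) and Fasn (0.0501 to 0.0641 without TRACK-VAD 2 or WT-VAD 1, 2 or 3) lost their calls without 1 library (adjusted p). The lane term ended the calls of Atf3 (1.11), Btg2 (0.94), Ccnb2 (0.88), Slco1a1 (-0.47), Cyp2a4 (-0.52), Bco2 (-0.61), Dhrs3 (-0.39), Arntl (0.47), Nr1d2 (-0.31) and Fasn (0.85), given as log2 with lane. Without scaling Dhrs3 and Nr1d2 were not called.

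**Figure D3:**
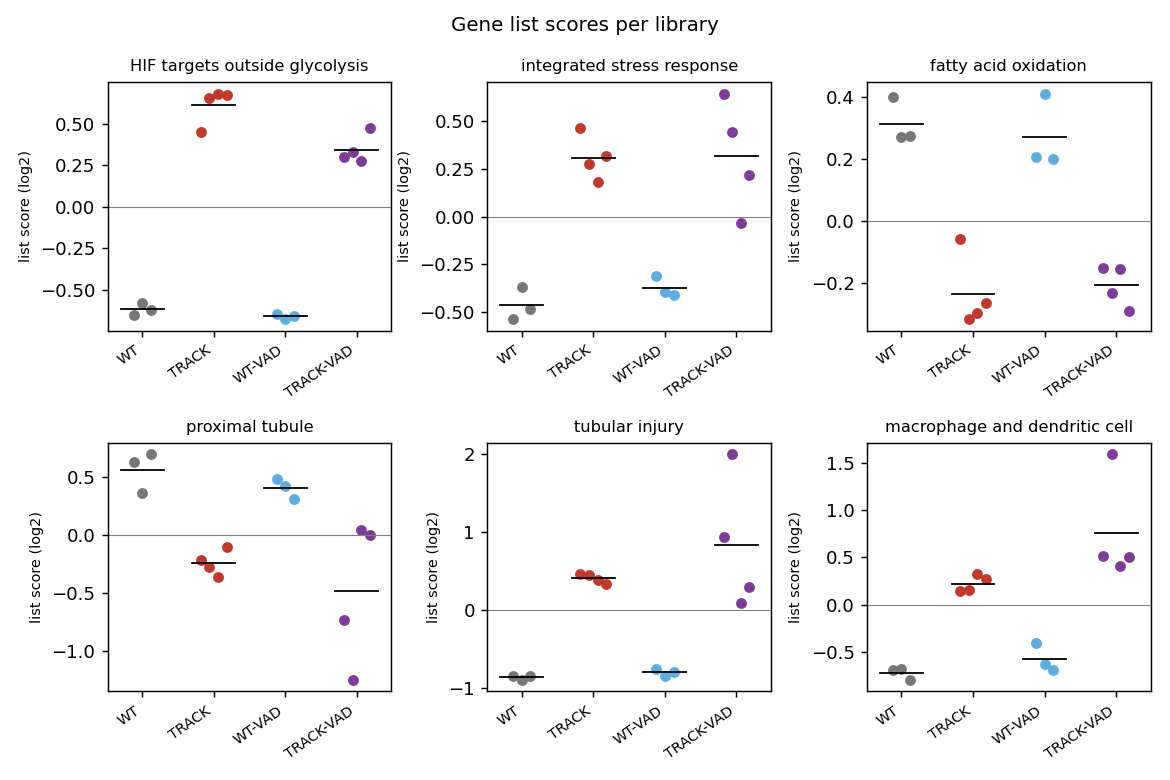
Scores of 6 gene lists per library (mean log2 deviation of members from the mean of all 14 libraries) for WT, TRACK, WT-VAD and TRACK-VAD; points are libraries and lines are group means. HIF target scores were above 0 in all 8 transgenic and below 0 in all 6 wild-type libraries, and tubular injury scores of TRACK-VAD spread from 0.10 to 2.00.

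The genotype difference went the same way on both diets for most called genes, in comparisons that share no library. Of 2087 genes called on chow, 1992 (95.4%) had the same sign on the deficient diet, against 74.6% of all genes tested. Limma called 1273 genes on both diets, and 1269 of these had the same sign: 660 were higher and 609 lower on both, where independent lists would share 122 and 109. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.759 and a Spearman correlation of 0.678. Averaged over diets, 4363 genes differed between 8 transgenic and 6 wild-type libraries, 2206 higher and 2157 lower (50.6% higher, or 83.8% of 5333 without scaling); with lane as a term the count was 1948. Limma called 1 gene for the difference between the genotype effects, which does not exclude large differences (989 at an unadjusted p at or under 0.05). That gene, Aox1, an aldehyde oxidase chosen after its values were seen, had 0.0632, 1.42, 0.162 and 0.34 FPKM in WT, TRACK, WT-VAD and TRACK-VAD. With 1 library left out the interaction count was 0 without WT 1 or 3, TRACK 1, 2 or 4, TRACK-VAD 3 or WT-VAD 2 or 3 (687 to 1422 genes at an unadjusted p at or under 0.05), 2 without WT 2 or TRACK 3, 3 without TRACK-VAD 2, 7 without TRACK-VAD 4 and 6 without WT-VAD 1. It was also 0 with lane as a term, the replicate block, a pseudocount of 0.1 or a filter at 5 FPKM.

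The diet was compared within wild-type mice to ask what vitamin A deficiency changes without the transgene. Cyp26b1 (ENSMUSG00000063415, chromosome 6, 84571414 to 84593908), which encodes an enzyme that degrades retinoic acid and is induced by it, fell from 4.78 ± 0.858 FPKM (SD, n = 3) to 0.843 ± 0.479 FPKM (SD, n = 3) (log2 fold change -1.67 ± 0.24 (SE), adjusted p = 0.0114). Circadian clock genes moved in both directions: Dbp rose from 12.2 ± 4.24 FPKM to 61.8 ± 6.58 FPKM (log2 fold change 2.29 ± 0.26 (SE), adjusted p = 0.00306) and Ciart (2.02, adjusted p = 0.021) rose, while Arntl (-1.59, adjusted p = 0.00684), which encodes BMAL1, and Npas2 (-1.37, adjusted p = 0.00391) fell. Calcium-handling genes of the distal nephron, Calb1 (-1.55, adjusted p = 0.0174) and S100g (-1.37, adjusted p = 0.0272), and Slc16a1 (-1.38, adjusted p = 0.00115) also fell, and Ugt2b37 (1.63, adjusted p = 0.0212), Hspb8 (1.24, adjusted p = 0.0238), Tgm1 (1.20, adjusted p = 0.0168) and Pcsk4 (1.19, adjusted p = 0.021) rose. Of the 17 circadian clock genes, 3 rose and 2 fell, or 7 and 4 adjusted over the list alone, and fry's test of change in either direction gave an adjusted p of 2.27e-05. For circadian clock genes camera pointed up (adjusted p = 0.253). Of the 22 retinoid genes, 1 fell, or 1 higher and 2 lower adjusted over the list alone. For retinoid genes camera pointed down (adjusted p = 0.192). Rarb (-0.15), Stra6 (-0.28), Lrat (-0.21) and Dhrs3 (-0.40) had adjusted p of 0.665, 0.923, 0.676 and 0.138. Dbp, Npas2 and Slc16a1 kept their calls with any 1 library left out; S100g was not called without scaling. Ciart (0.0626 to 0.114 without WT 1, 2 or 3 or WT-VAD 2 or 3), Ugt2b37 (0.0559 to 0.116 without WT 1, 2 or 3 or WT-VAD 1, 2 or 3), Hspb8 (0.0536 to 0.113 without WT 1, 2 or 3 or WT-VAD 1, 2 or 3), Tgm1 (0.072 to 0.0931 without WT 1 or 3 or WT-VAD 2 or 3) and Pcsk4 (0.0917 to 0.118 without WT 1 or 3 or WT-VAD 2 or 3) lost their calls without 1 library (adjusted p). Cyp26b1 (0.0501 to 0.0842 without WT 1 or 3 or WT-VAD 2), Arntl (0.0534 to 0.0565 without WT 1 or WT-VAD 2 or 3), Calb1 (0.0893 to 0.0989 without WT 1 or 3 or WT-VAD 2 or 3) and S100g (0.0696 to 0.139 without WT 1, 2 or 3 or WT-VAD 1, 2 or 3) lost their calls in the same way. With lane as a term, which widened the SE 1.73 times (median over genes), none of these genes was called; the log2 fold changes were then Dbp (1.86), Ciart (1.65), Ugt2b37 (1.40), Hspb8 (1.35), Tgm1 (0.84), Pcsk4 (1.40), Cyp26b1 (-1.33), Arntl (-1.20), Calb1 (-1.85), Slc16a1 (-1.66), Npas2 (-1.37) and S100g (-0.42).

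Of the 29 other HIF target genes, 2 rose and 2 fell, or 3 and 3 adjusted over the list alone, Bhlhe40 (1.14, adjusted p = 0.0168) and Tfrc (0.91, adjusted p = 0.0468) being higher and Slc16a1 and Ndrg1 (-0.99, adjusted p = 0.0114) lower. For other HIF target genes camera pointed down (adjusted p = 0.571). Among mitochondrial and stress lists, Clpx (-1.07, adjusted p = 0.014) and Sesn2 (-0.95, adjusted p = 0.0174) fell; the integrated stress response list had a camera adjusted p of 0.607, and Atf4 (0.32), Atf5 (0.43) and Ddit3 (0.21) were not called. Median, mean and camera direction differed in sign for glycolysis, fatty acid oxidation, lipid and cholesterol synthesis, NRF2 targets, proximal tubule, female-biased kidney genes and perirenal fat and adrenal. Of the 17 endoplasmic reticulum chaperone genes, none passed limma's test over all genes, 2 higher and 0 lower did adjusted over the list alone, and 3 higher and 0 lower had an unadjusted p at or under 0.05. Camera pointed up (adjusted p = 0.0116, 0.96 with estimated correlation). Of the 16 collecting duct genes, none passed limma's test over all genes, 0 higher and 3 lower did adjusted over the list alone, and 1 higher and 7 lower had an unadjusted p at or under 0.05. Camera pointed down (adjusted p = 0.0254, 0.96 with estimated correlation). Limma called 63 genes between WT-VAD and WT, 27 higher and 36 lower. All WT libraries are in lane 5 and all WT-VAD libraries in lane 6, so lane and diet cannot be told apart by this comparison alone; with lane as a term, estimated from the TRACK-VAD libraries, limma called 0 genes, with 1060 at an unadjusted p at or under 0.05. The count was 40 with no filter, 146 with these groups alone, and 5, 8, 41, 5 and 5 without WT 1, WT 3, WT-VAD 1, 2 and 3. Bhlhe40 (0.0501 to 0.0989 without WT 1 or 3 or WT-VAD 1, 2 or 3), Tfrc (0.090 to 0.212 without WT 1 or 3 or WT-VAD 1, 2 or 3), Ndrg1 (0.0501 to 0.0757 without WT 1 or 3 or WT-VAD 2 or 3), Clpx (0.069 to 0.0931 without WT 1 or WT-VAD 2 or 3) and Sesn2 (0.072 to 0.101 without WT 1 or 3 or WT-VAD 2 or 3) lost their calls without 1 library (adjusted p). With lane the log2 fold changes were Bhlhe40 (0.54), Tfrc (0.71), Ndrg1 (-1.25), Clpx (-1.26) and Sesn2 (-0.95).

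Within transgenic mice, Cyp26b1 also fell on the deficient diet, from 8.56 ± 1.55 FPKM (SD, n = 4) to 0.751 ± 0.523 FPKM (SD, n = 4) (log2 fold change -2.48 ± 0.20 (SE), adjusted p = 0.000178). F2 fell from 71.3 ± 6.28 FPKM to 17.2 ± 8.68 FPKM (log2 fold change -2.12 ± 0.27 (SE), adjusted p = 0.00434), Rbp4 from 43.7 ± 3.41 FPKM to 11.3 ± 6.06 FPKM (log2 fold change -2.01 ± 0.32 (SE), adjusted p = 0.0259), and the carboxypeptidase gene Cpb2 (-1.76, adjusted p = 0.00434) fell, whereas Apoc3 (-1.10, adjusted p = 0.297) and Apoa4 (-1.85, adjusted p = 0.128) were not called. The transcriptional repressor gene Bcl6 (-1.96, adjusted p = 0.00434) fell, and Cish (1.06, adjusted p = 0.0429) rose. Cish (0.0521 to 0.181 without TRACK 1, 2 or 3 or TRACK-VAD 1, 2 or 3) and Rbp4 (0.0523 to 0.116 without TRACK 1, 2, 3 or 4 or TRACK-VAD 1 or 3) lost their calls without 1 library (adjusted p). With these groups alone, Cish, Cpb2, F2 and Rbp4 were not called. Atf4 (0.06), Atf5 (-0.26), Ddit3 (-0.08), Hspd1 (-0.09), Lonp1 (-0.24), Clpp (0.00), Rarb (-0.23), Stra6 (0.93), Lrat (-0.11) and Dhrs3 (-0.19) were not called. Of the 29 other HIF target genes, none passed limma's test over all genes, 0 higher and 15 lower did adjusted over the list alone, and 0 higher and 16 lower had an unadjusted p at or under 0.05. For other HIF target genes camera pointed down (adjusted p = 2.74e-08, 0.276 with estimated correlation). Of the 19 glycolysis genes, none passed limma's test over all genes, 0 higher and 1 lower did adjusted over the list alone, and 0 higher and 4 lower had an unadjusted p at or under 0.05. For glycolysis genes camera pointed down (adjusted p = 1.07e-06, 0.461 with estimated correlation). Of the 20 interferon response genes, none passed limma's test over all genes, 15 higher and 0 lower did adjusted over the list alone, and 15 higher and 0 lower had an unadjusted p at or under 0.05. For interferon response genes camera pointed up (adjusted p = 2.19e-14, 0.276 with estimated correlation). Of the 19 macrophage and dendritic cell genes, none passed limma's test over all genes, 10 higher and 0 lower did adjusted over the list alone, and 13 higher and 0 lower had an unadjusted p at or under 0.05. Camera pointed up (adjusted p = 1.78e-09, 0.461 with estimated correlation). Of the 16 collecting duct genes, none passed limma's test over all genes, 0 higher and 3 lower did adjusted over the list alone, and 0 higher and 9 lower had an unadjusted p at or under 0.05. For collecting duct genes camera pointed down (adjusted p = 8.08e-07, 0.276 with estimated correlation). Camera with the preset correlation also called other lists (adjusted p, then that with estimated correlation). Those down were gluconeogenesis (0.00236, 0.552), serine and one-carbon metabolism (0.00253, 0.281), proximal tubule (0.00822, 0.832) and loop of Henle and distal tubule (0.0161, 0.832). Tubular injury (0.00421, 0.832) was up. Median, mean and camera direction differed in sign for complex I, lipid and cholesterol synthesis, retinoid signalling and storage and circadian clock. TRACK-VAD libraries 1 and 2 stood apart in injury and proximal tubule scores. Their collecting duct scores were -0.20 and -0.61, against 0.12 and -0.01 in libraries 3 and 4. Interferon scores were 0.71 and 1.19 against 0.52 and 0.25.

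Limma called 19 genes between TRACK-VAD and TRACK, 1 higher and 18 lower, with 1288 genes at an unadjusted p at or under 0.05. The count was 56 with lane as a term, 3 with these groups alone, 10 and 29 with pseudocounts of 0.1 and 5, and 9, 10, 10, 10 and 58 without TRACK 2, 3, 4 and TRACK-VAD 1 and 4.

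Averaged over genotypes, with 7 libraries per diet, 112 genes were called, 39 higher and 73 lower on the deficient diet. The count was 3 with lane as a term, 62 with no filter, 287 without TRACK-VAD 1 and 2, and 40 to 73 without any 1 of the WT, TRACK and WT-VAD libraries or TRACK-VAD 1. Between TRACK-VAD and WT, which differ in genotype and diet, 2943 genes were called (51.4% higher, or 83.4% of 3619 without scaling), 1174 with these groups alone, 1698 without TRACK-VAD 1 and 2, and 1671 without WT 1 and 1531 without WT 3. Between TRACK and WT-VAD 2112 were called (50.5% higher, or 77.2% of 2204), 248 with lane as a term, and 1306 without TRACK 3, 1359 without WT-VAD 1 and 1142 without WT-VAD 2.

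**Figure D4:**
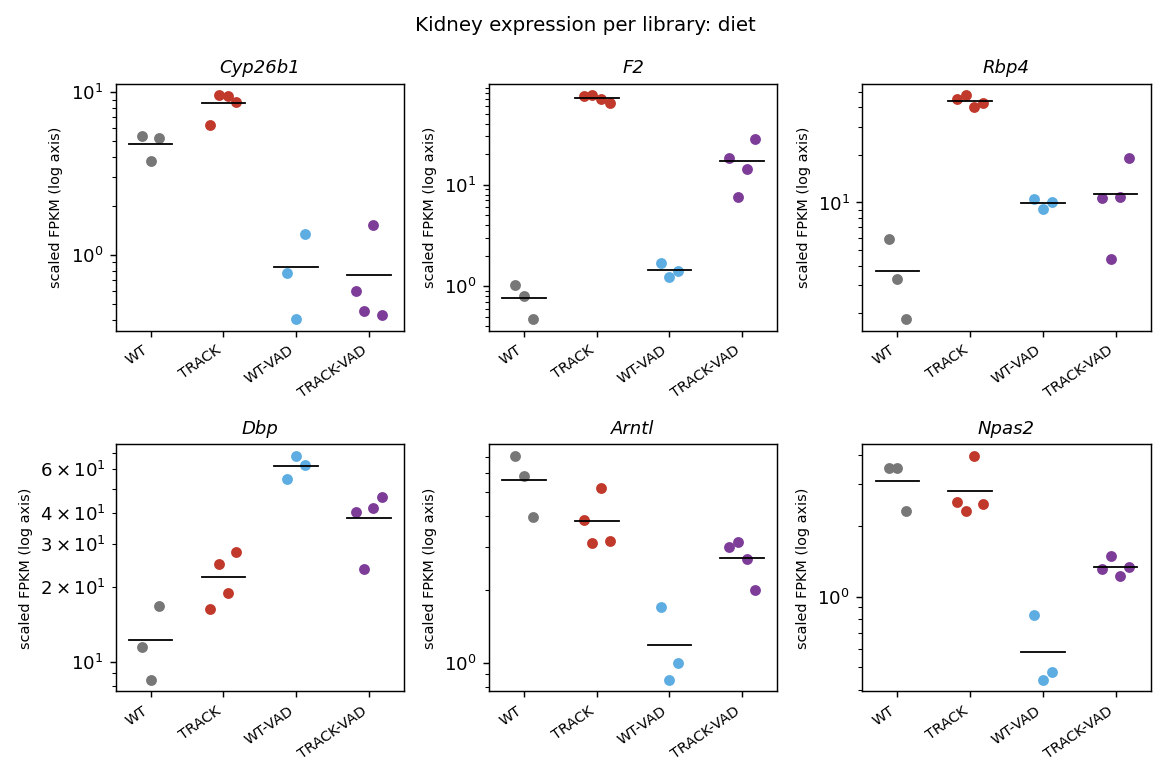
Scaled FPKM (log axis) of 6 genes in each library of WT, TRACK, WT-VAD and TRACK-VAD; points are libraries and lines are group means. Cyp26b1 was lower in every library on the deficient diet than in every library on chow; Dbp, Arntl and Npas2 differed between the wild-type groups, which were read in different lanes.

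The authors' deposited tables, made from counts of 42687 genes of all classes, call more genes: 4014, 4836, 342, 210, 5070 and 4063 for TRACK against WT, TRACK-VAD against WT-VAD, WT-VAD against WT, TRACK-VAD against TRACK, TRACK-VAD against WT and TRACK against WT-VAD. Of the genes called by limma on FPKM, 1914, 2513, 58, 19, 2723 and 1945 are also called in the authors' deposited tables, all with the same sign except for 1 gene in TRACK-VAD against WT-VAD. Both come from the same reads, so this overlap is no independent check.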

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

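The tests of the plasma protein genes, the clock genes and the TRACK-VAD libraries were chosen after these results were seen. Among group values of the genes and lists named, tested in the groups of 4 libraries, 26 of 338 had 1 library far from the other 3, where chance gives 16.9. Of these, 14 lay in TRACK and 12 in TRACK-VAD, 9 of them in TRACK-VAD library 2. The library was the highest, in scaled FPKM, for Cyp2e1 in TRACK 4 (667, next 431), Cyp26b1 in TRACK-VAD 3 (1.53, next 0.599), Npas2 in TRACK 3 (3.98, next 2.52), S100g in TRACK 3 (1778, next 1506), Slc16a3 in TRACK 2 (32.5, next 24.9), Trib3 in TRACK 1 (13.8, next 9.48), Acaa1b in TRACK 1 (159.7, next 131), Rarg in TRACK 2 (15.8, next 6.47), Lyz2 in TRACK-VAD 2 (91.2, next 38.9), H2-Ab1 in TRACK-VAD 2 (313, next 138), Ccl5 in TRACK-VAD 2 (33.9, next 10.9), Slc7a12 in TRACK 2 (19.2, next 14), Acly in TRACK-VAD 4 (82.9, next 67) and Krt20 in TRACK-VAD 2 (26.5, next 4.51). It was the lowest for Pink1 in TRACK-VAD 2 (166, next 190.5), Aldh18a1 in TRACK 4 (18.5, next 21.3), Insig1 in TRACK 1 (5.45, next 8.77), Acly in TRACK 1 (73.6, next 92.9) and Cldn16 in TRACK 4 (10.8, next 13). List scores (log2) stood apart for HIF targets outside glycolysis in TRACK 1 (0.452, next 0.652), mitochondrial chaperones and proteases in TRACK-VAD 2 (-0.25, next -0.0817), macrophage and dendritic cell in TRACK-VAD 2 (1.59, next 0.519), lymphocyte in TRACK-VAD 2 (1.01, next 0.367), fibroblast and extracellular matrix in TRACK-VAD 2 (0.772, next 0.132), cell cycle in TRACK-VAD 3 (-0.0673, next 0.125) and perirenal fat and adrenal in TRACK 4 (4.48, next -0.20).

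Aox1 had an interaction of -0.98 (log2, limma, adjusted p = 0.0173). Camera called an interaction for 4 lists: glycolysis (adjusted p = 0.00234), HIF targets outside glycolysis (0.00566), macrophage and dendritic cell (0.00429) and interferon response (0.000118); with an estimated correlation each had an adjusted p of 0.966.

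The plasma protein genes F2, Apoc3, Apoa4, Cpb2 and Rbp4 were higher in TRACK than in WT kidneys on chow, with a median log2 fold change of 5.29, within a single lane, which argues against a lane effect. RNA from liver in the TRACK samples would bring abundant hepatocyte transcripts, yet the 26 tested had a median of 0.26 (quartiles -0.00556 to 0.431), with 3 called higher (Gc, Trf and Rbp4, the last in both sets) and 1 lower. The albumin gene Alb was at -0.20, so liver RNA is argued against as well. A hypothesis that stays open is expression of these genes in the transgenic kidney, which may depend on vitamin A. The interaction with diet was not called for any of the 5 (limma, adjusted p = 0.0747 for Rbp4, 0.0819 for F2 and Cpb2, 0.359 for Apoa4 and 0.574 for Apoc3).

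Between WT-VAD and WT, limma called 3 of 10 genes of a Dbp arm of the clock higher (Dbp, Ciart and Nr1d2) and 2 of 4 of an Arntl arm lower (Arntl and Npas2). The arms were written after these genes were seen, so the difference between arm means, 1.81 higher in WT-VAD (log2), does not test a shift of clock phase, which stays open. A diet effect alike in both genotypes and a lane effect cannot be told apart: the difference was 0.49 in TRACK mice (exact permutation p = 0.0857) and the interaction -1.32 ± 0.36 (SE), but lane separates the wild-type groups. TRACK-VAD library 4, in the lane of the WT-VAD libraries, lay at 0.57, beyond the other TRACK-VAD libraries (-0.317 to 0.428), but this is 1 library. The hour at which kidneys were taken, not given in the labels, may differ between groups and was not tested.

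TRACK-VAD libraries 1 and 2 stood apart from 3 and 4 in injury and proximal tubule scores, library 2 alone in macrophage score. More medulla in these pieces stays open: collecting duct, loop of Henle and proximal tubule scores all lay below those of libraries 3 and 4. Exchange with a wild-type library is argued against by their HIF target scores, the lower at 0.30, while wild-type libraries lay at -0.676 to -0.581. Lane is argued against, since the other 8 libraries in their lane had injury scores of -0.895 to 0.465, below the 0.935 and 2.0 of libraries 1 and 2. The labels give nothing that separates these mice, so no biological explanation was tested.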

How the results depend on the processing

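No scaling, a filter at 5 FPKM, keeping estimates listed at 0 and leaving out TRACK-VAD 1 and 2 were chosen after the data were seen. Median-ratio scaling, keeping estimates listed at 0 and the filter at 5 FPKM left every count of called genes within 1.5 times, except that limma called 0 genes for the interaction with the last. Lane as a term gave 221 genes for TRACK-VAD against WT-VAD, 1948 for the genotype average, 248 for TRACK against WT-VAD, 56 for TRACK-VAD against TRACK, 3 for the diet average and 0 for WT-VAD against WT (1060 at an unadjusted p at or under 0.05). Fits of only the groups compared gave 3377 genes for TRACK against WT, 576 for TRACK-VAD against WT-VAD, 146 for WT-VAD against WT, 3 for TRACK-VAD against TRACK and 1174 for TRACK-VAD against WT. Without TRACK-VAD 1 and 2 the counts were 1277 for TRACK-VAD against WT-VAD, 1698 for TRACK-VAD against WT, 287 for the diet average and 3 for the interaction. With no filter, 40 were called for WT-VAD against WT and 62 for the diet average. For TRACK-VAD against TRACK, pseudocounts of 0.1 and 5 gave 10 and 29. The interaction had 3 genes with a pseudocount of 5, 4 without scaling and 0 with a pseudocount of 0.1, the block, lane or the filter at 5 FPKM, where 990, 1141, 511 and 723 genes had an unadjusted p at or under 0.05. Over all genes 74.6% had the same sign on both diets. With 1 library left out, counts ran from 1004 to 1876 for TRACK against WT, 1569 to 3453 for TRACK-VAD against WT-VAD, 5 to 43 for WT-VAD against WT, 9 to 58 for TRACK-VAD against TRACK, 3559 to 4734 for the genotype average, 40 to 167 for the diet average, 0 to 7 for the interaction, 1531 to 3602 for TRACK-VAD against WT and 1142 to 1816 for TRACK against WT-VAD. Except for fewer libraries or genes, the cause was not tested.

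Replicate numbers did not pair the samples: deviations of 19 same-number pairs correlated at -0.142 to 0.382, 6 of them over 0.1. With the number as a block, 7 genes were called for TRACK-VAD against TRACK and 0 for the interaction, and other counts stayed within 1.5 times. Of 214 results of named genes, 181 were called and 0 of those changed sign (limma, any alternative); 68 lost the call without some 1 library, 78 with lane, 30 with no filter, 28 without scaling, 10 with the block, 49 of 178 with the groups alone and 29 of 85 without TRACK-VAD 1 and 2. Results that changed sign had not been called: with lane Hif1a 0.0233 and Stra6 -0.0569 in TRACK-VAD against WT-VAD, Stra6 0.882 in WT-VAD against WT, Clpp 0.00611 in TRACK-VAD against TRACK; without scaling Hif1a 0.104 in TRACK against WT, Hif1a 0.124 and Clpp 0.0585 in TRACK-VAD against WT-VAD, Clpp 0.0455 in TRACK-VAD against TRACK; without TRACK-VAD 1 and 2 Hif1a 0.0949 in TRACK-VAD against WT-VAD, Hif1a 0.0695, Atf4 -0.173 and Hspd1 0.061 in TRACK-VAD against TRACK; with median-ratio scaling Clpp 0.00195 in TRACK-VAD against TRACK; with these groups alone Clpp 0.00157 in TRACK-VAD against TRACK (log2). Their ranges with 1 library left out were Hif1a -0.12 to 0.00186 in TRACK against WT; Hif1a -0.199 to 0.0461 and Lonp1 -0.00668 to 0.155 in TRACK-VAD against WT-VAD; Hif1a -0.216 to 0.0294 and Lonp1 -0.0822 to 0.0313 in WT-VAD against WT; Atf4 -0.0306 to 0.136, Ddit3 -0.331 to 0.0726, Hspd1 -0.159 to 0.00782 and Clpp -0.0437 to 0.0229 in TRACK-VAD against TRACK. Gene lists that changed direction had adjusted p as follows: with lane gluconeogenesis 0.0682, retinoid signalling and storage 0.879, loop of Henle and distal tubule 0.185, collecting duct 0.711 and circadian clock 0.628 in TRACK-VAD against WT-VAD, glycolysis 0.000229, mitochondrial chaperones and proteases 0.727, fatty acid oxidation 0.648, NRF2 targets 0.648, fibroblast and extracellular matrix 0.648, cell cycle 0.648, circadian clock 0.909, male-biased kidney genes 0.0457 and muscle and blood 0.82 in WT-VAD against WT, circadian clock 0.827 in TRACK-VAD against TRACK; with fry gluconeogenesis 0.918 in TRACK-VAD against WT-VAD, perirenal fat and adrenal 0.998 in WT-VAD against WT, complex I 0.968 and circadian clock 0.968 in TRACK-VAD against TRACK; with the replicate block endoplasmic reticulum chaperones 0.791 in TRACK-VAD against WT-VAD. The lane term rests on TRACK-VAD 4 against 1 to 3. Their male-biased scores were 0.11 against -0.66, -1.28 and 0.11, so reversals with this term need not reflect lane. In the order TRACK against WT, TRACK-VAD against WT-VAD, WT-VAD against WT and TRACK-VAD against TRACK, 20, 20, 2 and 10 lists were called. These became 1, 0, 0 and 0 with correlation estimated, 20, 23, 13 and 14 with lane and 18, 20, 0 and 1 with fry. The planned count-based tool was not run because the values are FPKM, and the planned minimum of 1 CPM became that of 1 FPKM. Absolute depth per library is unknown, so no limit from counting can be given.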

Other observations

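The comparisons with other splits of the samples were planned, and the account of hepatocyte transcripts was chosen after the data were seen. Of 26 genes whose abundant source is the liver, limma called 3 higher and 1 lower in TRACK than in WT kidneys on chow. Gc rose on chow (2.93, adjusted p = 8.02e-05) and on the deficient diet (adjusted p = 0.000119, and 2.89 with lane as a term). Rbp4 and Trf rose on chow; for Trf (1.05, adjusted p = 0.0378) the call ended without WT 1, 2 or 3 or TRACK 2 (adjusted p = 0.0534 to 0.152), and the fold change was 0.66 without TRACK 4, at 131 FPKM against 38.2 to 53.8 in other TRACK libraries. Apoh fell on chow, from 16 to 22.3 FPKM in WT to 3.82 to 7.44 in TRACK libraries (-1.66, adjusted p = 0.00803). On the deficient diet 1 was called higher and 7 lower, but 1 and 0 with lane as a term and 2 and 1 without TRACK-VAD 1 and 2. Alb, one of them (-2.01, adjusted p = 0.0455), had 3.49, 6.95, 35.5 and 34.6 FPKM in TRACK-VAD libraries 1 to 4, 55.4 to 60.2 in WT-VAD and 18.4 to 39.5 in WT, and the call ended without TRACK-VAD 1 or 2 or any WT-VAD library (adjusted p = 0.0999 to 0.114).

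Limma was rerun on other splits of the same libraries. For TRACK against WT, 1 of 35 splits, the real one, gave as many as 2087 genes. The highest other gave 469, so chance alone is unlikely. The same holds for TRACK-VAD against TRACK (1 of 35, 19 genes, highest other 11) and TRACK against WT-VAD (1 of 35, 2112, 326). It also holds for the averages of genotype (1 of 100, 4363, 968) and diet (1 of 100, 112, 1). For TRACK-VAD against WT 1 of 35 gave 2943 genes, but another, with TRACK-VAD 3 placed among WT, gave 2909, so the margin is small. For TRACK-VAD against WT-VAD, 2 of 35 splits gave at least 2707 genes, the other giving 2864 with TRACK-VAD 3 placed among WT-VAD, so chance cannot be excluded by this count. For the interaction, 5 of 100 splits gave at least 1 gene, so chance cannot be excluded; 1 of them exchanged the diets of all TRACK mice, which turns the contrast into the diet average, and gave its 112 genes. For WT-VAD against WT, with 63 genes and 0 as the highest other of 10 splits, the splits are too few for a share under 0.05.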
